A study of Oryza sativa with 24 samples.

How the data were processed

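Seedling shoots of rice at the 4-leaf stage, grown for 4 weeks, were profiled in 4 lines per the labels: the japonica cultivar Nipponbare, the indica cultivar 93-11, and the reciprocal F1 hybrids named Nipponbare/93-11 and 93-11/Nipponbare. The labels do not say which name in a hybrid's label is the seed parent, so both names are used as given. The DNA methylation libraries came from an enrichment of methylated genomic DNA with digestion by McrBC, an enzyme that cuts methylated DNA, and chromatin was immunoprecipitated with antibodies against H3K4me3, H3K9ac and H3K27me3, per the labels' protocols. The labels list 24 samples. The 16 DNA methylation and histone libraries, 1 for each mark and line, have a peak list and were analysed, and the 8 mRNA and small RNA samples were not analysed here.

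Each deposited file lists peak regions of 1 library in 3 columns with no header, giving chromosome, start and end. The authors' lists hold no height, score or p-value, so every peak of a list was treated alike and peak width took the place of a score, by a rule fixed in advance. The aligner, the peak caller, its threshold, any control library and the genome build are not given in the sources used here. All 16 lists name the same 12 nuclear chromosomes, with last peaks that end near each other, and some also hold peaks on C (plastid) and M (mitochondrion), so the 4 lines were compared on 1 coordinate system. Positions are printed as the files give them. The smallest start is 1, and whether positions count from 0 or 1 is not stated in the files; width is end minus start. The number of reads behind a list is unknown, so no statement about read depth is made, and the length of a list depends on depth and threshold in ways that were not separable. Rows can have been left out of the lists used here, so a region missing from a list is described as not listed.

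Gene annotation was not used. The Nipponbare H3K4me3 peaks overlapped protein-coding genes of an annotation of a newer Nipponbare assembly (ASM3414082v1) in 42.4% of cases as given and in 41.4 to 42.5% after moving them by 50 to 200 kb in 6 offsets. Its coordinates were therefore taken to belong to another build, and the planned counts of genes with each mark, gene lists and cell type markers were not computed. Peaks took the place of genes, as the rule fixed beforehand provided.

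A peak was counted as shared with another list when it overlapped one of its peaks by at least 1 bp. Shares are given with exact Clopper-Pearson 95% intervals, which cover counting error only. There was 1 library for each mark and line, so no difference between lines was tested and no p-value is given; a difference beyond these intervals is one between 2 libraries. Chance overlap was described by moving the second list along each chromosome by a random circular shift, 100 times. Peaks of a parent with no overlap in the other parent's list are called Nipponbare-only or 93-11-only. For presence in all 4 lines, the 4 lists of a mark were merged into regions. Densities were counted in windows of 1 Mb and correlations between lists over windows of 100 kb; windows are not independent replicates. Runs were defined, after seeing the data, as 5 or more consecutive H3K4me3 peaks of a parent with none shared with the other parent, and were set against 1000 permutations of which peaks of a chromosome were unshared.

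Named regions followed a rule fixed before the data were examined: per mark, the 3 widest peaks in Nipponbare and both hybrids and not in 93-11, and the 3 of the mirror set; the 2 widest in both hybrids and neither parent; the 2 widest in both parents and neither hybrid; the 2 widest in each hybrid alone; and the 3 widest for each pair of marks described in Nipponbare. Regions from the runs and the widest peaks of a list were chosen after their values were seen.

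Peaks on the plastid and mitochondrial sequences were kept in the totals and left out of densities, runs and comparisons by chromosome. Alternatives were a 50% reciprocal overlap, lists kept at or above their own median width (both lists for sharing, the hybrid lists alone for peaks in neither parent, the list of the parent alone for single-parent peaks), lists shortened to the length of the shortest of a mark, and merging of peaks under 500 bp apart. The overlap routine was tested on simulated data: copies of the Nipponbare H3K4me3 list of 28273 peaks thinned to 50.6, 69.6 and 90.1% gave shared percentages of 50.6, 69.6 and 90.1, and 400 of 400 peaks checked by direct comparison were equal. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.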

Results

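The 16 peak lists covered DNA methylation, H3K4me3, H3K9ac and H3K27me3 in shoots of Nipponbare, 93-11 and their 2 reciprocal hybrids, with 1 library for each mark and line and therefore no replicate error. H3K4me3 and H3K9ac are marks of active promoters, and H3K27me3 is the mark set by Polycomb complexes at repressed genes. DNA methylation lists held 22332 (93-11) to 24695 (93-11/Nipponbare) peaks, H3K4me3 lists 27526 (93-11) to 30697 (Nipponbare/93-11), H3K9ac lists 28737 (93-11) to 31943 (Nipponbare/93-11) and H3K27me3 lists 17479 (Nipponbare) to 20460 (93-11/Nipponbare). Peaks covered between 28.4 Mb (H3K27me3 in Nipponbare) and 49.4 Mb (H3K9ac in Nipponbare/93-11) of the 372 Mb spanned by the lists. Median peak widths lay between 1354 and 1609 bp. Read depth is unknown, so differences in list length between lines cannot be read as differences in the amount of a mark.

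Active marks and DNA methylation were arranged in opposite ways along the chromosomes of Nipponbare. H3K4me3 peaks were densest on chromosome 3 (91.6 per Mb) and sparsest on chromosome 12 (62.4 per Mb) and chromosome 11 (63.8 per Mb). DNA methylation peaks were sparsest on chromosome 3 (54.4 per Mb) and densest on chromosome 11 (73.7 per Mb). In 93-11, H3K4me3 ranged from 91.9 peaks per Mb on chromosome 3 to 57.6 on chromosome 12, and DNA methylation from 54.1 per Mb on chromosome 1 to 64.5 on chromosome 7, with 60.3 on chromosome 12. Across 3726 windows of 100 kb, the numbers of H3K4me3 and H3K9ac peaks had a Pearson correlation of 0.921 (Spearman 0.923) in Nipponbare, and H3K4me3 and DNA methylation one of -0.374 (Spearman -0.388). The latter was -0.131 (Spearman -0.140) in 93-11, -0.190 (Spearman -0.203) in Nipponbare/93-11 and -0.210 (Spearman -0.222) in 93-11/Nipponbare. These correlations, among 48 computed, are across windows, which are not independent replicates.

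**Figure D1:**
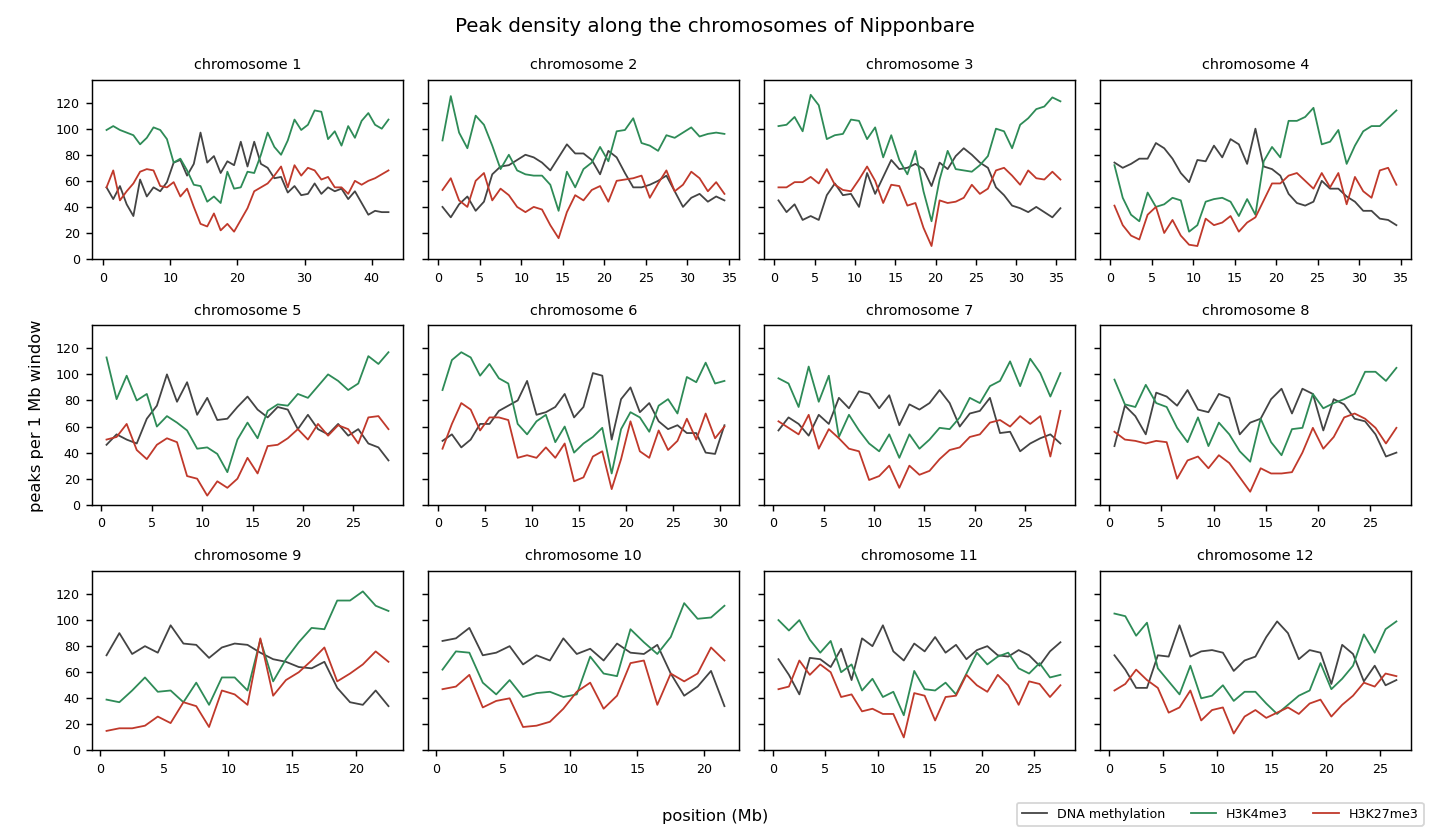
Number of peaks per 1 Mb window (y axis) along the position in Mb (x axis) of the 12 nuclear chromosomes in the Nipponbare lists, with 1 line each for DNA methylation, H3K4me3 and H3K27me3; the incomplete last window of each chromosome is left out. DNA methylation tends to be high where H3K4me3 is low, with a Pearson correlation of -0.374 over windows of 100 kb.

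H3K4me3 and H3K9ac occupied largely the same regions in every line. In Nipponbare, 92.3% of H3K4me3 peaks (95% interval 92.0 to 92.6%) overlapped an H3K9ac peak, against a mean of 25.0% after circular shifts, and in the other lines 92.2% (93-11), 93.1% (Nipponbare/93-11) and 90.9% (93-11/Nipponbare). H3K27me3 peaks also lay mostly on H3K4me3 peaks: 75.2% (74.5 to 75.8%) did so in Nipponbare, against 23.1% after shifts, and 74.3% in 93-11. An H3K9ac peak was overlapped by 78.6% of H3K27me3 peaks in Nipponbare, against 26.0% after shifts, and by 77.2% in 93-11. H3K4me3 peaks with both H3K9ac and H3K27me3 made up 43.7% of the Nipponbare list, and those with H3K9ac and no H3K27me3 48.6%. H3K4me3 peaks rarely carried DNA methylation: 7.79% (7.48 to 8.11%) overlapped in Nipponbare against 20.6% after shifts, and 12.1% in 93-11/Nipponbare against 23.1%.

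The widest H3K4me3 peak of Nipponbare, on chromosome 5 from 27523213 to 27531926 (8713 bp), carried H3K4me3, H3K9ac and H3K27me3 in all 4 lines and DNA methylation in 93-11 alone. The second widest, on chromosome 2 from 28709483 to 28716283, was listed for H3K4me3 in Nipponbare alone, with DNA methylation in all 4 lines. On chromosome 4, the region from 22092822 to 22098438 had H3K4me3 and H3K27me3 in all 4 lines and H3K9ac in all but 93-11. On chromosome 1, the region from 28898378 to 28902610 (4232 bp) had all 4 marks in all 4 lines. An H3K27me3 peak with DNA methylation on chromosome 7 from 1446186 to 1452144 had H3K27me3 in Nipponbare alone, while DNA methylation and H3K4me3 were listed in all 4 lines. Overlapping peaks within a line come from separate libraries of whole shoots and do not show that marks lie on the same molecules. No list of a control library was available, so overlap common to any immunoprecipitated library was not measured. The share of H3K4me3 peaks with DNA methylation was 0.711% when a 50% overlap in both directions was required, and 4.26% between lists of peaks of at least the median width.

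The parents' lists shared most peaks of the active marks and far fewer of DNA methylation. H3K4me3 was shared most, with 86.6% of Nipponbare peaks (86.2 to 87.0%) listed in 93-11 and 88.9% in the other direction. H3K9ac followed with 83.0% (82.6 to 83.4%) and 87.8%, and H3K27me3 with 77.7% (77.1 to 78.3%) and 72.4%. DNA methylation was shared least, at 54.2% (53.6 to 54.8%) and 58.3%. Between the hybrids, which hold the same genomes, 79.1% of DNA methylation and 93.8% of H3K4me3 peaks of Nipponbare/93-11 were shared. The low share of DNA methylation between parents therefore need not all be a difference between their genomes. Shifted lists gave 21.7, 24.4, 16.2 and 20.8% for the Nipponbare peaks of H3K4me3, H3K9ac, H3K27me3 and DNA methylation. Of the merged regions, 73.4% of 32707 H3K4me3 regions were listed in all 4 lines, as were 67.7% of 35360 for H3K9ac, 49.6% of 25567 for H3K27me3 and 29.8% of 37466 for DNA methylation.

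**Figure D2:**
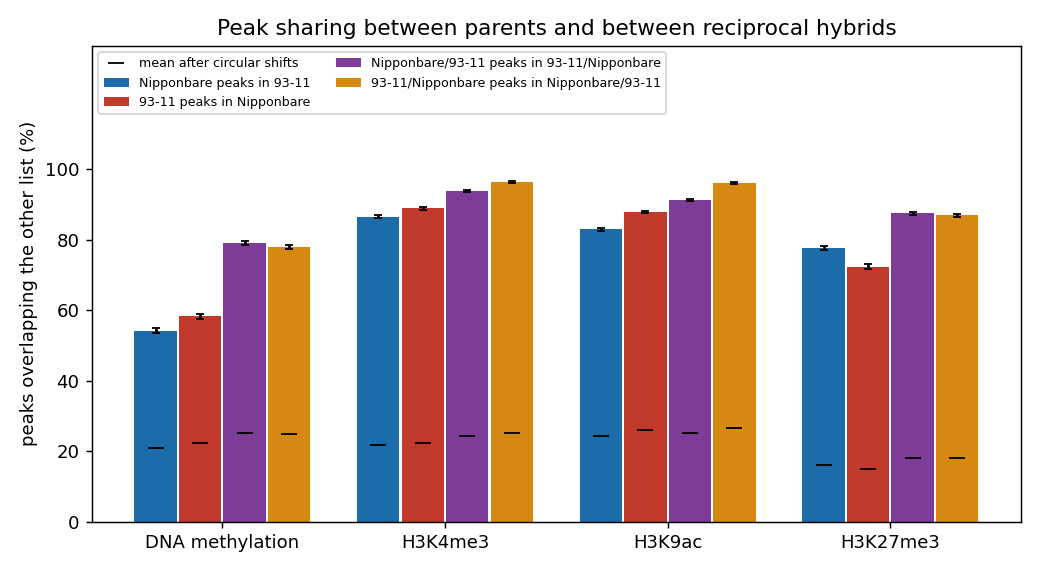
Percentage of each list's peaks (y axis) that overlap the other list by at least 1 bp, for the 4 marks (x axis), between the parents and between the reciprocal hybrids. Bars are shares with exact 95% binomial intervals and dashes the means of 100 circular shifts; DNA methylation has the lowest bars in each comparison, 54.2% for Nipponbare peaks in 93-11 and 79.1% for Nipponbare/93-11 peaks in 93-11/Nipponbare.

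Chromosomes 11 and 12 held the largest shares of Nipponbare-only active peaks. On chromosome 11, 20.7% (18.9 to 22.6%) of Nipponbare H3K4me3 peaks were not listed in 93-11, and on chromosome 12 19.5% (17.6 to 21.4%), against 9.25% (8.29 to 10.3%) on chromosome 3. H3K9ac had 25.1% on chromosome 11 and 24.0% on chromosome 12 against 12.6% on chromosome 3, and H3K27me3 28.9 and 27.5% against 17.9%. In the opposite direction, 93-11-only H3K4me3 peaks made up 12.7% (11.1 to 14.4%) of the list on chromosome 11 and 9.79% (8.81 to 10.9%) on chromosome 3. Nipponbare-only DNA methylation peaks lay between 42.5% on chromosome 2 and 1049 of 2098 peaks (47.8 to 52.2%) on chromosome 11.

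**Figure D3:**
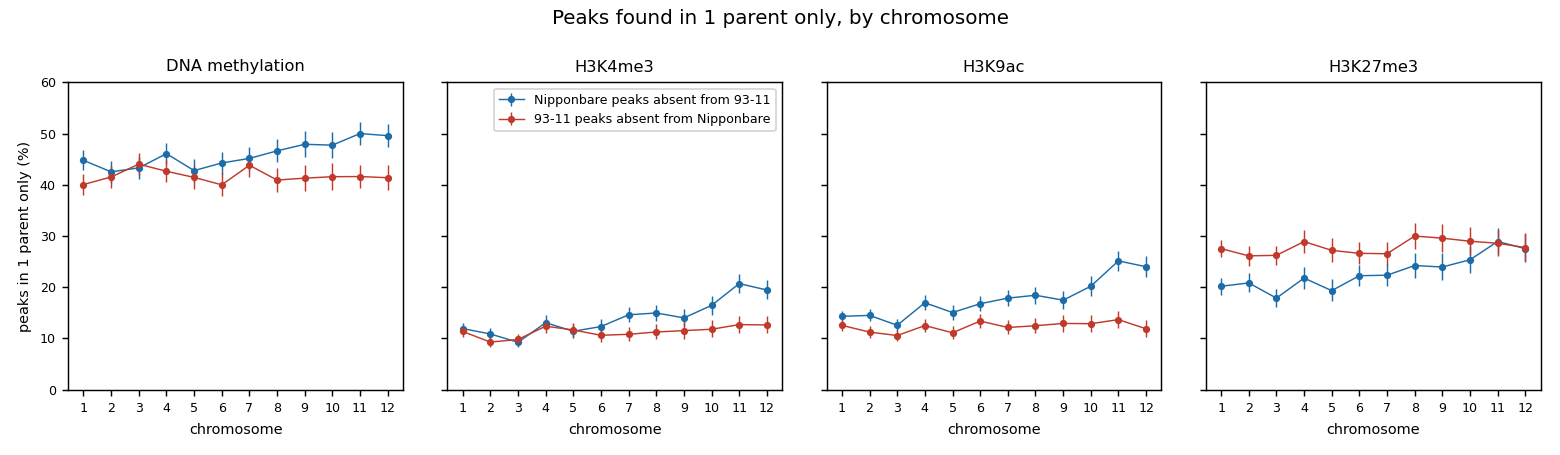
Percentage of a parent's peaks with no overlap in the other parent (y axis) on each of the 12 nuclear chromosomes (x axis), 1 panel per mark, with exact 95% binomial intervals. For H3K4me3, the Nipponbare-only share is 9.25% on chromosome 3 and 20.7% on chromosome 11, while the 93-11-only share is 9.79 and 12.7%.

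At H3K4me3 peaks of 1 parent alone, H3K9ac was listed less often in the parent without H3K4me3, and more so for Nipponbare-only than for 93-11-only peaks. Of the 3792 Nipponbare-only H3K4me3 peaks, 86.3% (85.2 to 87.4%) carried H3K9ac in Nipponbare and 15.3% (14.1 to 16.5%) in 93-11. At the H3K4me3 peaks that 93-11 shared, H3K9ac was listed on 93.2% in Nipponbare and 94.6% in 93-11. The 3063 93-11-only H3K4me3 peaks carried H3K9ac in 73.1% of cases in 93-11 and in 39.3% (37.5 to 41.0%) in Nipponbare. H3K27me3 lay on 41.9% of Nipponbare-only H3K4me3 peaks in Nipponbare and on 13.9% in 93-11. DNA methylation was listed on 16.0% (14.7 to 17.3%) of 93-11-only H3K4me3 peaks in Nipponbare, where H3K4me3 was not listed, and on 7.51% (6.60 to 8.50%) in 93-11. At Nipponbare-only H3K4me3 peaks these shares were 13.7% (12.6 to 14.8%) in 93-11 and 11.3% (10.3 to 12.3%) in Nipponbare. Shared H3K4me3 peaks of the 93-11 list had DNA methylation on 7.45% in Nipponbare and 9.81% in 93-11, and those of the Nipponbare list on 7.25 and 9.35%. Shifted DNA methylation lists gave 20.6% at all H3K4me3 peaks of Nipponbare and 19.2% at those of 93-11, above each of these shares. Single-parent peaks were narrower than shared ones, with medians of 1192 and 1380 bp in the Nipponbare H3K4me3 list.

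Regions of single-parent state that both hybrids also carried were named by width. For H3K27me3, the region on chromosome 12 from 23966670 to 23976956 (10286 bp) was the widest Nipponbare peak and carried H3K4me3 and H3K9ac in the same 3 lines, with no histone mark listed in 93-11. The region on chromosome 8 from 7249687 to 7256333 (6646 bp) had that pattern for the 3 histone marks too. On chromosome 7 from 18686646 to 18691103 (4457 bp), H3K4me3 and H3K9ac were listed in 93-11 and both hybrids and not in Nipponbare, with H3K27me3 in the hybrids alone. On chromosome 2 from 30346540 to 30351218 (4678 bp), H3K9ac, H3K4me3 and DNA methylation were all listed in 93-11 and both hybrids and none of them in Nipponbare. On chromosome 1 from 42510346 to 42514795 (4449 bp), H3K4me3 and H3K9ac were listed in 93-11 and both hybrids, and H3K27me3 in all 4 lines.

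At several other named regions, fewer marks separated the parents. On chromosome 10 from 4889446 to 4900064 (10618 bp) and on chromosome 1 from 30667028 to 30674084 (7056 bp), H3K27me3 was listed in 93-11 and both hybrids while H3K4me3 and H3K9ac were listed in all 4 lines. On chromosome 6 from 28866587 to 28871464 (4877 bp), H3K4me3 was not listed in Nipponbare, where H3K9ac and H3K27me3 were. On chromosome 7 from 28847230 to 28853515 (6285 bp), H3K9ac was not listed in 93-11, where H3K4me3 and H3K27me3 were. For DNA methylation, the widest such Nipponbare peaks lay on chromosome 8 from 13569385 to 13579716 (10331 bp) and chromosome 7 from 18009782 to 18018017 (8235 bp), with no histone peak in any line. The widest in 93-11 lay on chromosome 9 from 13437971 to 13455682 (17711 bp) and overlapped H3K4me3 and H3K9ac in all 4 lines and H3K27me3 in 93-11 and both hybrids. Of the widest 1% of Nipponbare DNA methylation peaks, 71.8% (65.6 to 77.4%) were not listed in 93-11, against 42.3% in the ninth of 10 width classes, and of the widest 1% of H3K27me3 peaks 26.4% (20.1 to 33.6%) against 10.2%. For H3K4me3 and H3K9ac, 11.0% (7.59 to 15.2%) and 9.57% (6.50 to 13.5%) were not listed, against 8.17 and 9.86% in the ninth class. Of all Nipponbare peaks, 45.8% for DNA methylation, 22.3% for H3K27me3, 13.4% for H3K4me3 and 17.0% for H3K9ac were not listed in 93-11.

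Some unshared H3K4me3 peaks stood next to each other in blocks. Nipponbare had 47 runs of 5 or more consecutive Nipponbare-only peaks, holding 283 peaks, where permutations gave a mean of 1.60 runs and at most 7. Chromosomes 11 and 12 held 13 of the 47. The run with most peaks lay on chromosome 12 from 8230991 to 8521130 (290 kb), with 10 H3K4me3 peaks in Nipponbare, 0 in 93-11, 10 in Nipponbare/93-11 and 4 in 93-11/Nipponbare. H3K9ac peaks there numbered 11, 0, 11 and 9, H3K27me3 peaks 10, 0, 8 and 6, and DNA methylation peaks 30, 14, 25 and 25 in the same order. On chromosome 11 from 21056267 to 21149571, Nipponbare had 7 H3K4me3 and 7 H3K9ac peaks and 93-11 had 0 of either. On chromosome 1 from 41729583 to 41838075, Nipponbare had 7 H3K4me3, 7 H3K9ac and 5 H3K27me3 peaks, all 3 at 0 in 93-11, and 7 DNA methylation peaks against 1. On chromosome 7 from 14869605 to 15189921 (320 kb), DNA methylation was nearly level, with 22 peaks in Nipponbare and 21 in 93-11, while H3K4me3 had 8 and 2.

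In the mirror direction 93-11 had 2 runs, where permutations gave a mean of 0.426 and at most 3. The longer, on chromosome 1 from 14816394 to 15171847 (355 kb), held 10 H3K4me3 peaks in 93-11 and 6 in Nipponbare at other positions. Those 6 Nipponbare peaks formed a Nipponbare-only run from 14817241 to 14948227 on the same chromosome. The other lay on chromosome 10 from 4836769 to 4872233, with 5 H3K4me3 peaks in 93-11, 0 in Nipponbare and 4 in each hybrid. Over the 47 Nipponbare runs together, H3K4me3 peaks numbered 283 in Nipponbare, 17 in 93-11, 270 in Nipponbare/93-11 and 233 in 93-11/Nipponbare. H3K9ac peaks numbered 300, 36, 263 and 238, H3K27me3 peaks 170, 53, 156 and 150, and DNA methylation peaks 373, 238, 277 and 294. In 14 of the 47 runs, 93-11 had as many DNA methylation peaks as Nipponbare or more. The definition of runs was chosen after the data were seen.

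**Figure D4:**
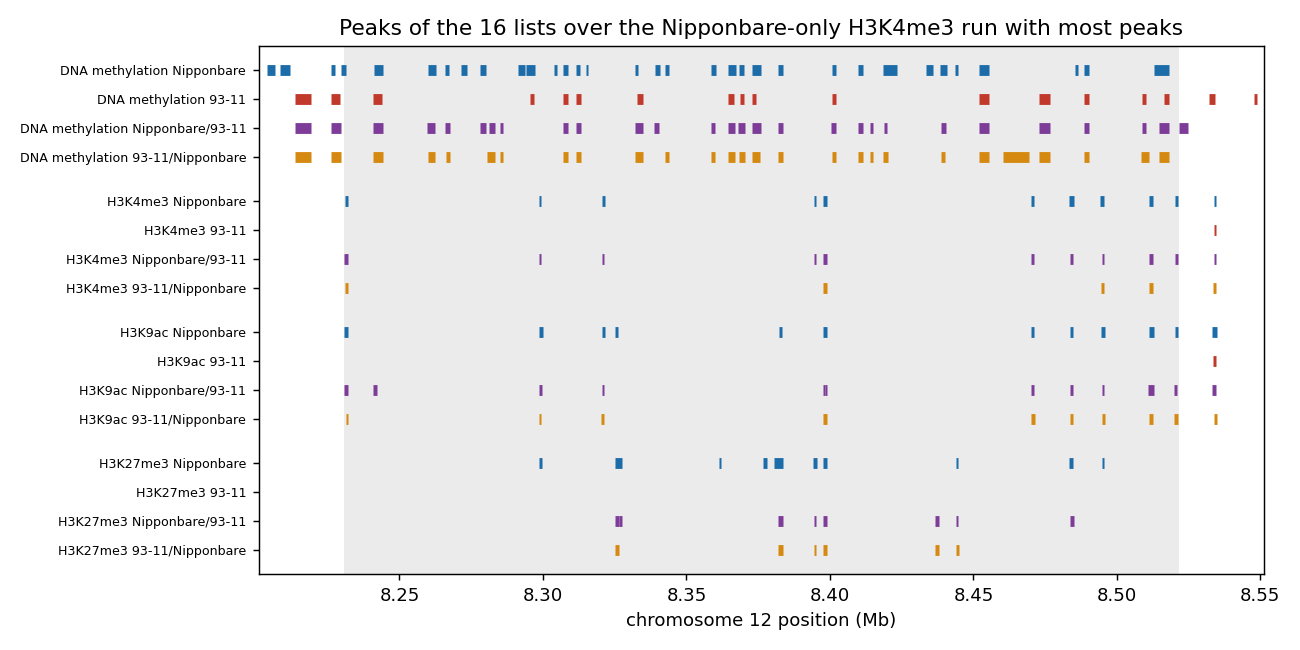
Peaks of the 16 lists (y axis, 1 row per mark and line) over chromosome 12 (x axis, position in Mb), with the Nipponbare-only H3K4me3 run from 8230991 to 8521130 shaded; each bar is 1 peak drawn to scale. The 93-11 rows hold 0 peaks of H3K4me3, H3K9ac and H3K27me3 in the run and 14 of DNA methylation.

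Nipponbare-only DNA methylation peaks were listed in both hybrids least often of the 4 marks, while the 93-11-only peaks of the 4 marks lay between 47.0 and 58.1%. Both hybrids listed 65.0% (63.5 to 66.5%) of Nipponbare-only and 58.1% (56.4 to 59.9%) of 93-11-only H3K4me3 peaks. For H3K9ac the shares were 54.6% (53.3 to 56.0%) and 49.1% (47.4 to 50.8%), and for H3K27me3 47.3% (45.7 to 48.8%) and 47.0% (45.6 to 48.4%). Of Nipponbare-only DNA methylation peaks 24.3% (23.5 to 25.1%) were in both hybrids, against 48.0% (47.0 to 49.0%) of 93-11-only peaks. Neither hybrid listed 46.0% of Nipponbare-only DNA methylation peaks, against 24.3% of 93-11-only ones and 14.3% of Nipponbare-only H3K4me3 peaks. Circular shifts were not run for single-parent peaks, so the part of these shares due to chance overlap is unknown.

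**Figure D5:**
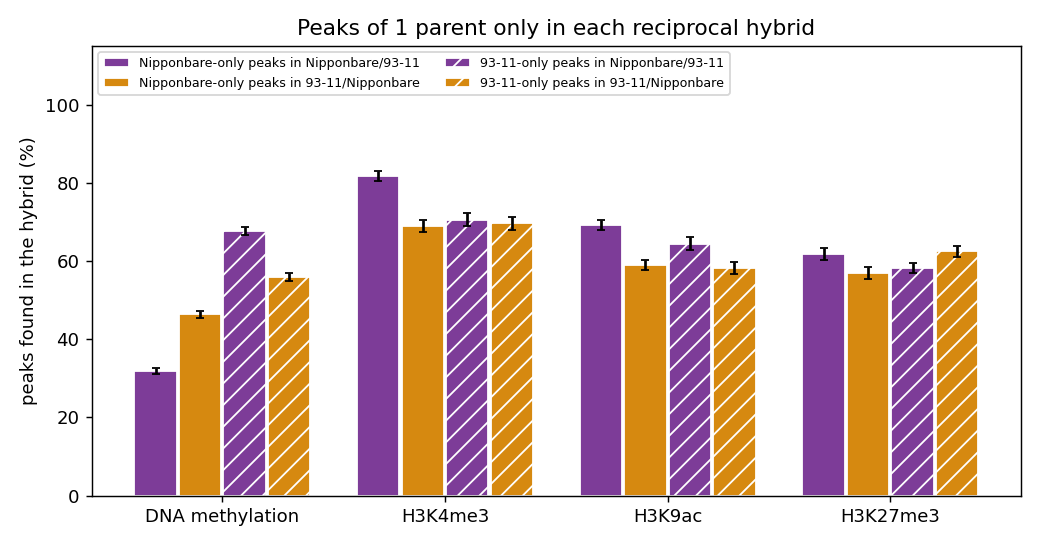
Percentage of Nipponbare-only (plain bars) and 93-11-only (hatched bars) peaks listed in each reciprocal hybrid (y axis) for the 4 marks (x axis), with exact 95% binomial intervals. For DNA methylation, the library labelled Nipponbare/93-11 lists 31.9% of Nipponbare-only and 67.7% of 93-11-only peaks, and that labelled 93-11/Nipponbare 46.3 and 56.0%, a direction that an exchange of the labels would turn.

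Few hybrid peaks of the active marks lay outside both parents' lists, and more did for H3K27me3 and DNA methylation. An overlap of 1 bp with either parental list took a peak out of this class. Circular shifts were not run for it, so chance overlap lowers these shares by an unknown part. For H3K4me3, 3.81% (3.60 to 4.04%) of Nipponbare/93-11 peaks and 2.98% (2.79 to 3.17%) of 93-11/Nipponbare peaks lay outside both lists. For H3K9ac these shares were 4.05 and 3.11%. H3K27me3 had 9.50% (9.10 to 9.92%) and 9.76%, and DNA methylation 12.7% (12.3 to 13.1%) and 10.1%. The other hybrid also listed 39.7% of such H3K4me3 peaks of Nipponbare/93-11 and 35.0% of its DNA methylation peaks. They were narrow, with a median of 979 bp for H3K4me3 in Nipponbare/93-11 against 1380 bp for its other peaks. Peaks shared by the parents were seldom missing from both hybrids: 0.241% (0.184 to 0.311%) of H3K4me3, 1.13% of H3K9ac, 1.47% of H3K27me3 and 3.92% (3.59 to 4.26%) of DNA methylation peaks in the Nipponbare list. Among peaks of at least the median width, the share of both hybrids' peaks in neither parent was 1.22% for H3K4me3 (3.40% of all), 1.69% for H3K9ac (3.59% of all) and 3.73% for H3K27me3 (9.63% of all).

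The widest H3K4me3 region of both hybrids and neither parent lay on chromosome 9 from 15279684 to 15284678 (4994 bp), with H3K9ac in both hybrids and 93-11. Next came chromosome 3 from 30147329 to 30151471 (4142 bp), with H3K27me3 in both hybrids and Nipponbare. For H3K27me3 these were chromosome 3 from 30609346 to 30616824 (7478 bp) and chromosome 7 from 23876721 to 23884176 (7455 bp), and H3K4me3 and H3K9ac were listed in all 4 lines at both. A DNA methylation region on chromosome 9 from 2787791 to 2861187 (73396 bp) in Nipponbare/93-11 overlapped no peak of a parent and no histone peak, and the 93-11/Nipponbare peak there reached to 2885478 and did overlap a 93-11 peak. Of regions in both parents and neither hybrid, the widest for H3K4me3 lay on chromosome 9 from 12368538 to 12372317 (3779 bp), where DNA methylation was listed in Nipponbare and both hybrids. For H3K9ac it lay on chromosome 1 from 1702116 to 1706081 (3965 bp) with no other mark in any line, and for H3K27me3 on chromosome 9 from 7994175 to 7999997 (5822 bp), where both hybrids had DNA methylation.

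The reciprocal hybrids were closer to each other than the parents were for each mark. Of Nipponbare/93-11 peaks, 93.8% (93.5 to 94.0%) of H3K4me3, 91.2% (90.9 to 91.5%) of H3K9ac, 87.5% (87.0 to 87.9%) of H3K27me3 and 79.1% (78.6 to 79.6%) of DNA methylation peaks were listed in 93-11/Nipponbare. In the other direction the shares were 96.4, 96.1, 87.0 and 78.0%. The 2 libraries labelled as hybrids differed in which parent's DNA methylation peaks they listed. That of Nipponbare/93-11 listed 31.9% (31.0 to 32.8%) of Nipponbare-only and 67.7% (66.7 to 68.6%) of 93-11-only peaks, and that of 93-11/Nipponbare 46.3% (45.4 to 47.3%) and 56.0% (5215 of 9315). This direction rests on the labels and would turn if those of the 2 DNA methylation libraries were exchanged. H3K4me3 differed the opposite way: Nipponbare/93-11 listed 81.7% (80.5 to 82.9%) of Nipponbare-only peaks and 93-11/Nipponbare 69.0% (67.5 to 70.4%), while 93-11-only peaks were at 70.6 and 69.7%. For H3K9ac, Nipponbare-only peaks were at 69.2 and 59.0% and 93-11-only peaks at 64.4 and 58.2%, and for H3K27me3 at 61.8 and 56.9% and at 58.2 and 62.4%. In the widest of 4 width classes, where fewer H3K4me3 peaks were unshared, Nipponbare/93-11 listed 90.1% of Nipponbare-only and 82.1% of 93-11-only peaks and 93-11/Nipponbare 82.4 and 80.0%. Circular shifts were not run for single-parent peaks. Between whole DNA methylation lists, of the parents or of the hybrids, their means were 20.8 to 25.3%. Part of the DNA methylation shares can therefore be chance overlap. The counting intervals exclude neither a difference between 2 library preparations nor one in read depth.

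Regions listed in 1 hybrid alone of the 4 lines were few for H3K4me3 and more for DNA methylation. Merged regions in Nipponbare/93-11 alone numbered 706 for H3K4me3, 769 for H3K9ac, 1066 for H3K27me3 and 2010 for DNA methylation, and in 93-11/Nipponbare alone 429, 431, 1131 and 1420. The widest H3K4me3 peak of 93-11/Nipponbare alone lay at the start of chromosome 9, from 3 to 36957 (36954 bp), with no other mark in any line. It is an outlier: the next widest peak of the whole list was 6560 bp, and 90.9% of the list's peaks carried H3K9ac. Whether it reflects the mark was not tested. The next peak of 93-11/Nipponbare alone lay on chromosome 1 from 8519460 to 8523419 (3959 bp). In Nipponbare/93-11 alone, H3K4me3 was listed on chromosome 12 from 27427799 to 27432340 (4541 bp), where H3K9ac and H3K27me3 were listed in all 4 lines. H3K27me3 was listed in Nipponbare/93-11 alone on chromosome 2 from 31412963 to 31422265 (9302 bp) and in 93-11/Nipponbare alone on chromosome 1 from 1619597 to 1625052 (5455 bp). DNA methylation was listed in Nipponbare/93-11 alone on chromosome 9 from 2570175 to 2585157 (14982 bp) and in 93-11/Nipponbare alone on chromosome 11 from 10636555 to 10656982 (20427 bp) and on the mitochondrial sequence from 62450 to 83024. Of the widest 1% of Nipponbare/93-11 DNA methylation peaks, 55.6% (49.1 to 61.9%) were not listed in 93-11/Nipponbare, against 16.3% in the ninth of 10 width classes.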

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

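The tests of explanations in this part and the bounds they were held to were all chosen after the results were seen, and some replaced earlier forms: the widest peaks were first compared between single-parent and other peaks, a count of chromosomes, set first against parental blocks and then for mixed parental tissue, was dropped because any difference along the whole genome gives it, and the bound for narrow peaks was changed, which left its outcome as it was. DNA methylation lists held peaks on the plastid and mitochondrial sequences, which the comparisons by chromosome left out. They numbered 7 in Nipponbare, 12 in 93-11, 6 in Nipponbare/93-11 and 13 in 93-11/Nipponbare, each above a fixed floor of 3. That floor is not a level expected by chance, so no excess over the nuclear chromosomes is meant. For H3K4me3, the share of Nipponbare-only peaks listed in a hybrid minus that of 93-11-only peaks was 11.1 percentage points in Nipponbare/93-11 and -0.709 in 93-11/Nipponbare. For H3K27me3 it was 3.52 and -5.57 percentage points. These pairs stand out because the sign differs between the hybrids. With 1 library each, the difference was not tested. For H3K4me3 in 93-11/Nipponbare the counting intervals of the 2 shares overlapped (67.5 to 70.4% and 68.0 to 71.3%), so that negative sign is not established. For H3K27me3 the intervals lay apart in each hybrid. In the widest of 4 width classes the sign was the same in both hybrids: Nipponbare/93-11 listed 90.1% of Nipponbare-only and 82.1% of 93-11-only H3K4me3 peaks and 93-11/Nipponbare 82.4 and 80.0%, and for H3K27me3 the shares were 77.3 and 68.9% and 77.3 and 72.6%.

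DNA methylation separated the hybrids most: the index that subtracts the hybrids' difference on 93-11-only peaks from that on Nipponbare-only peaks (Nipponbare/93-11 minus 93-11/Nipponbare) was -26.1 percentage points. Narrow peaks are argued against as the whole cause, since the index over the widest of 4 width classes was -24.3. The lists hold no score, so peaks near a calling threshold could not be told apart and their part stays open. An exchange of the labels of the DNA methylation hybrid libraries would turn the sign and stays open. All 3 histone marks had the opposite sign (11.8 for H3K4me3, 4.01 for H3K9ac and 9.08 for H3K27me3, or 5.62, 6.23 and 3.69 in the widest class). Whether DNA methylation should lean to the same parent as the histone marks is unknown, so the opposite signs do not point to an exchange. A parent-of-origin difference and tissue of a parent mixed into a hybrid library stay open and untested, because each hybrid has 1 library per mark.

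The widest 1% of peaks were missing from other lists more often than those in the ninth of 10 width classes, with intervals apart, in 12 of 12 comparisons between lines for DNA methylation and H3K27me3 and in 10 of 12 each for H3K4me3 and H3K9ac. Against all peaks of the list, and without regard to intervals, their share was higher in 12 of 12 comparisons for DNA methylation and for H3K27me3, but in 9 of 12 for H3K4me3 and 5 of 12 for H3K9ac, where of Nipponbare peaks 9.57% of the widest 1% and 17.0% of all were not listed in 93-11. A difference between the parental genomes is argued against as the whole cause for DNA methylation: the hybrids hold the same genomes, yet 55.6% of the widest 1% of Nipponbare/93-11 peaks were not listed in 93-11/Nipponbare, against 16.3% in the ninth of 10 width classes. Wide regions left out of single lists by the calling stay open as a cause. Between the hybrids, the widest 1% were missing more often than the ninth class in 8 of 8 comparisons, intervals apart (4 marks, both directions). These 8 are among the comparisons that make up the pattern, so they do not single out this cause. Rows left out of the lists used here stay open as another source, for which no test was possible.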

How the results depend on the processing

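The alternatives for overlap between marks were chosen after the data were seen, and the others beforehand. With no replicates, a share counted as moved when it left its 95% interval, a covered length when it changed at all, and a number of peaks when it changed by over 1.5 times. Of 90 alternative values 80 moved and 10 did not. Covered lengths, and peak numbers at the median width, were bound to move under these rules, so this tally does not measure stability. The 95% intervals are narrow because lists are long, so a moved share need not be a large change. DNA methylation stayed the least shared mark, between parents and between hybrids, under each alternative run. The order of the other marks changed under the median width alone: H3K27me3 then passed H3K9ac between parents, and H3K4me3 and H3K9ac between hybrids. Values below are in the order DNA methylation, H3K4me3, H3K9ac and H3K27me3 unless a mark is named, and the cause was not tested, except that by construction a stricter overlap lowers a share of shared peaks and the median width keeps the wider peaks of the lists it is applied to. It was applied to both lists for sharing between parents, between hybrids and between marks, to the hybrid lists alone for peaks in neither parent, and for single-parent peaks to the list of that parent alone, so these shares do not come from 1 common setting.

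With peaks of at least the median width, the 4 lists of a mark held 47775, 58175, 60679 and 38552 peaks over 124, 111, 120.3 and 85.0 Mb, against 179, 175, 190.9 and 127 Mb with all peaks; merging peaks under 500 bp apart gave 179.3, 175.5, 191.4 and 127.4 Mb. With 50% reciprocal overlap, Nipponbare peaks listed in 93-11 came to 48.8, 84.8, 80.8 and 74.8% and Nipponbare/93-11 peaks listed in 93-11/Nipponbare to 77.1, 92.4, 89.5 and 85.8%. Hybrid peaks in neither parent came to 14.5, 4.16, 4.88 and 11.1%, and of Nipponbare-only peaks 21.4, 61.0, 52.0 and 45.3% and of 93-11-only peaks 44.9, 53.5, 45.1 and 43.8% were in both hybrids. With the median width on both lists, shares were 48.2, 75.9, 70.9 and 75.7% between parents and 72.6, 81.1, 77.6 and 84.1% between hybrids. With it on the hybrid lists and whole parental lists, 8.63, 1.22, 1.69 and 3.73% were in neither parent, and with it on the one parental list and the others whole, 26.9, 80.0, 74.3 and 68.3% of Nipponbare-only and 51.7, 71.0, 64.5 and 60.3% of 93-11-only peaks were in both hybrids. With the 4 lists of a mark shortened to the length of the shortest by width, the shares were 55.2, 87.0, 84.3 and 74.8% between parents, 77.8, 93.0, 91.9 and 86.8% between hybrids, 10.5, 2.42, 2.93 and 6.96% in neither parent, and 22.9, 54.5, 51.3 and 35.1% and 40.4, 38.9, 38.0 and 38.6% in both hybrids. Merging moved the share between hybrids to 94.3% for H3K4me3 and 91.6% for H3K9ac. In Nipponbare, overlap of H3K4me3 with H3K9ac, of H3K27me3 with H3K4me3 and of H3K4me3 with DNA methylation was 77.4, 55.1 and 4.26% with the median width and 89.2, 66.8 and 0.711% with 50% reciprocal overlap.

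No paired analysis was possible because the labels carry no replicate numbers and each mark and line has 1 library. Alternatives on genes that were fixed in advance were not run, since no annotation on the lists' build was used: the gene body alone as window, and lists above their median width, for genes with each mark, co-occurrence of marks on genes and gene lists. Read depth is unknown for each list, so how far it limits the shares was not measured.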

Other observations

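The tests of explanations and the values in this part were chosen after the data were seen. H3K27me3 peaks without an active mark were narrower than the rest, with medians of 1360.5 and 1466 bp in Nipponbare and 1266 and 1465 bp in 93-11. From the narrowest to the widest of 4 width classes, 69.9, 75.8, 76.5 and 78.6% of Nipponbare H3K27me3 peaks overlapped H3K4me3 by 1 bp or more, 69.8, 75.4, 75.6 and 70.4% did so at their midpoint, and 68.3, 69.2, 63.4 and 54.0% of their bp were covered. Sharing between the parents and DNA methylation were not compared at equal width. In Nipponbare, 16.8% (16.2 to 17.3%) of H3K27me3 peaks overlapped neither H3K4me3 nor H3K9ac, and in 93-11 19.0% (18.5 to 19.6%). Of those in 93-11, 53.2% (51.6 to 54.9%) were listed in Nipponbare, against 76.9% (76.2 to 77.5%) of H3K27me3 peaks with an active mark; in the Nipponbare list 2050 of 2928 peaks without an active mark and 79.2% of those with one were listed in 93-11. DNA methylation lay on 16.2% (14.9 to 17.6%) of H3K27me3 peaks without an active mark and on 9.34% (8.87 to 9.82%) of those with one in Nipponbare, and on 21.8 and 12.4% in 93-11/Nipponbare. After moving H3K27me3 peaks of Nipponbare by 5 to 20 kb in either direction, 24.2 to 26.4% overlapped H3K4me3, against 75.2% in place.

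Some DNA methylation peaks were far wider than the rest. The widest of each list were 86923 bp on chromosome 7 from 12185186 to 12272109 in Nipponbare, 88321 bp on chromosome 1 from 17071654 to 17159975 in Nipponbare/93-11 and 97687 bp on chromosome 9 from 2787791 to 2885478 in 93-11/Nipponbare, whereas in 93-11 the widest was 17711 bp. No histone peak of any line overlapped the first 3 of these. A region on chromosome 4 from 9745190 to 9827450 (82260 bp) was listed in 93-11/Nipponbare and overlapped DNA methylation in Nipponbare, again with no histone peak.

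The runs of consecutive Nipponbare-only H3K4me3 peaks may, over part of them, mark stretches of Nipponbare sequence that 93-11 lacks or that are too diverged to map. Peaks lost one by one, each equally likely within its chromosome, are argued against, since 47 runs were seen and at most 7 in 1000 permutations. The permutations were not matched on peak width or region. Of Nipponbare H3K4me3 peaks, 26.0% were unshared in the narrowest of 10 width classes and 5.73% in the widest. A lower sensitivity of the 93-11 list that varies with peak width or along a chromosome therefore stays open. Missing or unmappable sequence over the whole of every run is argued against only if peaks come from the place where they are listed. In 14 of the 47 runs, 93-11 had as many DNA methylation peaks as Nipponbare or more, and in 5 it had more H3K27me3 peaks. How reads that match several places were handled is not given, so the point is not settled, and single runs were not judged. Missing or unmappable sequence over part of the runs stays open. The ratio of 93-11 to Nipponbare DNA methylation peaks over all 47 runs was 0.638. Of 1000 random placements, 95% lay between 0.811 and 1.02. Nipponbare had 47 runs and 93-11 had 2, from 3792 and 3063 unshared H3K4me3 peaks. A difference in chromatin between the parents stays open and untested, and why the runs were so unequal between the parents was not tested either.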
